A study of Homo sapiens with 6 samples.

How the data were processed

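RNA sequencing was carried out on human cells that the titles and protocols of all 6 samples name MDA-MB-231, an established adherent line of triple-negative breast cancer, after 4 h with 500 nM of compound 28 or after DMSO, for which no time is given. The series title describes compound 28 as a degrader of CDK9; CDK9 is the kinase of P-TEFb, which releases RNA polymerase II from promoter-proximal pausing. There were 6 libraries, 3 per group, and the group of each came from its title. The source and cell line labels run from MDA-MB-231 to MDA-MB-236, 1 number higher with each sample, so the labels conflict with the titles, and the name in the titles is used. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded kit that selects polyadenylated RNA. Per the submitters' processing notes, fastp, HISAT2, StringTie, SAMtools and HTSeq were used, with the builds GRCh37 and hg19; versions, settings and the strand setting of the counting were not given in the sources used here.

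The deposited table held 32327 rows with a normalized signal for each library, which from the values is a read count per gene divided by 1 size factor per library. All values above 0 in each library were whole multiples of 1 step, with 100% whole within 0.01 read, so the read counts could be recovered. The factors equalled median-of-ratios factors computed here over all rows. Per the file headers, the authors also deposited a log2 fold change with its standard error, a test statistic (a score equal to the log2 fold change divided by its error), and a raw and an adjusted p-value for each row. These columns were used only where the authors' deposited table is named. The deposited mean signal over all libraries was not used.

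The table held 5 rows that name no gene, with the names of the HTSeq summary counters, among the genes. They held 30.4% to 32.8% of all reads in the DMSO libraries and 40.4% to 46.9% in the compound 28 libraries and were left out of library totals and tests. A further 54 rows were not used here. Another 8 rows carried names that look like calendar dates, were kept in the tests and were not named. Of the 32268 rows used, 95.6% were matched by symbol to GENCODE release 29, which was used only for biotypes, lengths and the order of neighbouring genes, because its build, GRCh38, differs from that of the submitters. RefSeq on GRCh38.p14 was used for 1 neighbourhood, and no coordinates are printed.

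The test written down before the data were examined was edgeR's quasi-likelihood test if the values were counts, and limma-trend on log2(value + 1) if they were not. Because the table held normalized values, limma-trend on log2(normalized count + 1) was the main test, with the pseudocount 1, the normalization of the authors, the edgeR filter filterByExpr on the recovered reads, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale. The pseudocount understates the change of genes with low values, while averaging logs over unequal low values can overstate a fall, so that WNT6 fell 92.1-fold on this scale and 44.7-fold as a ratio of means. The filter left 18326 genes. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated for each list, over the 23 of 25 lists with at least 5 tested members. Estimation raised p even for called lists whose estimate lay below the preset, so a call lost with it does not by itself show correlated members. Camera was run on the same log2 values; log2 CPM with a prior count of 2, the scale written down beforehand, was run as an alternative. Camera compares test statistics, not folds, so a scaling that shifts all genes alike can change its calls while the list's difference in fold from other genes stays. Ranges of adjusted p over the alternatives leave out the estimated correlation, which is given separately, and the self-contained test fry. Members of each list were counted as called over all genes and adjusted over the list alone. The lists and the rule for named genes were fixed before the data were examined. The rule took CDK9, MYC, MCL1 and HEXIM1. It added the 4 largest rises and the 4 largest falls among called genes with at least 10 CPM in the higher group, no overlap of the groups and a symbol that is not a clone name. It further took the called members of each main list with the largest rise and the largest fall at 5 CPM or more, and the most abundant member of each context list. Where no member was called, the most abundant one was taken. That gave 47 genes. Other genes named in the text are list examples chosen after their values were seen.

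Alternatives covered library sizes only, TMM, upper-quartile and recomputed median-of-ratios factors, scaling on the 13 mitochondrially encoded mRNAs and on 82 ribosomal protein mRNAs, DESeq2 and limma-voom on recovered reads, other filters and pseudocounts, edgeR's glmTreat against a 1.5-fold minimum, protein-coding genes only, the replicate number as a block, and each library left out in turn. The scalings were applied in the limma-trend fit. EdgeR's quasi-likelihood test on the recovered reads, and camera on other scalings, were added after seeing the data. EdgeR's test called 13311 genes with TMM factors. DESeq2 run here on the recovered reads of all rows gave log2 fold changes within 0.001 of the deposited ones for 32266 of 32268 rows.

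In data simulated from the DMSO means and the library sizes over 18326 genes, limma-trend recovered 48% of 100 genes changed 2-fold. It recovered 91% of 100 genes changed 4-fold, and 2.80% of its calls were false. The simulated spread came from DMSO, and changes were planted only in genes above a minimum level. Far fewer genes changed there than the 13333 called here, so these shares need not hold for this comparison. Differences between single values of the libraries were tested with an exact permutation test, 2-sided, which cannot go below 0.1 with 3 libraries against 3. A group with 0 reads was given a floor of 3 reads over its 3 libraries. Intervals and floors cover counting error only, because PCR copies of 1 molecule cannot be told apart here. Within each group, every pair of libraries differed by more than counting noise, with a chi-square per degree of freedom of 13.1 to 61.1. Genes that share sequence with close copies, such as histone and ribosomal protein genes, pseudogenes and small RNAs, and genes that overlap another on either strand, are uncertain because the treatment of shared reads is not stated. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.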

Results

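RNA of cells titled MDA-MB-231 was sequenced after 4 h with 500 nM of compound 28 (3 libraries) or after DMSO (3 libraries), whose time is not given separately. Reads assigned to genes came to 54830987, 48175643 and 37186728 in DMSO replicates 1 to 3, and to 29248714, 34062330 and 28505897 in compound 28 replicates 1 to 3. Pearson's r was taken on log2(normalized count + 1) across genes with a mean of at least 1 CPM. It was 0.985 to 0.994 within DMSO, 0.986 to 0.989 within compound 28 and 0.788 to 0.815 between the groups. The first principal component separated the groups and held 92.2% of the variance.

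Compound 28 was compared with DMSO to ask which transcripts differ after 4 h with a compound described as a CDK9 degrader. MYC, a transcription factor that drives growth genes, fell from 14180 ± 2021 to 1178 ± 64.8 normalized counts (SD, n = 3; log2 change -3.58, adjusted p = 8.9e-09, limma). The largest falls by the rule for named genes were in TBX3, a T-box transcription factor (60.8-fold), DDIT3, a stress-response transcription factor (49.7-fold), BTG1, an antiproliferative gene (46.1-fold, 29.6-fold without compound 28 replicate 2), and WNT6, a secreted Wnt ligand. WNT6 fell from 343 ± 43.8 to 7.67 ± 12.2 normalized counts (SD, n = 3), which is 92.1-fold on the log2 scale and 44.7-fold as a ratio of means, and its place among the falls rests on single libraries, with 47.8-fold without compound 28 replicate 1 and 228-fold without replicate 3. The rule's largest rises, taken on the log2(value + 1) scale, were in MIR3648, LGR5, MIR3687 and KRT8P11, and their order depends on how values near 0 in DMSO are treated. MIR3648 went from 139 ± 57.5 to 169300 ± 39070 normalized counts and MIR3687 from 24.7 ± 7.24 to 21990 ± 2829 (SD, n = 3 each). LGR5, a receptor for R-spondins, had 0 reads in DMSO and 977 ± 114 normalized counts in compound 28 (SD, n = 3), at least 1443-fold higher against a floor of 3 reads over the 3 DMSO libraries. The keratin pseudogene KRT8P11 had 1 read in DMSO and 1180 reads in compound 28, a normalized ratio of 2468 with an exact counting interval of 442 to 97560.

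Of 18326 genes tested, 6522 rose and 6811 fell (adjusted p under 0.05, limma-trend). At 2-fold or more, 3898 rose and 4226 fell. At 16-fold or more the balance in the authors' normalization was different, with 674 genes higher and 209 lower, and at 64-fold or more 129 were higher and 8 lower. Genes of these size classes were not counted under other scalings, which shift all changes alike and can alter this balance. The groups did not overlap in 13878 genes, 75.7% of those tested, where chance gives 10%. Among protein-coding genes 2181 rose and 2974 fell at least 2-fold, whereas among processed pseudogenes 404 rose and 108 fell. The authors' deposited table holds 7729 higher and 6775 lower genes at the same threshold on the rows used, and 12731 genes were called in both with the same direction.

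**Figure D1:**
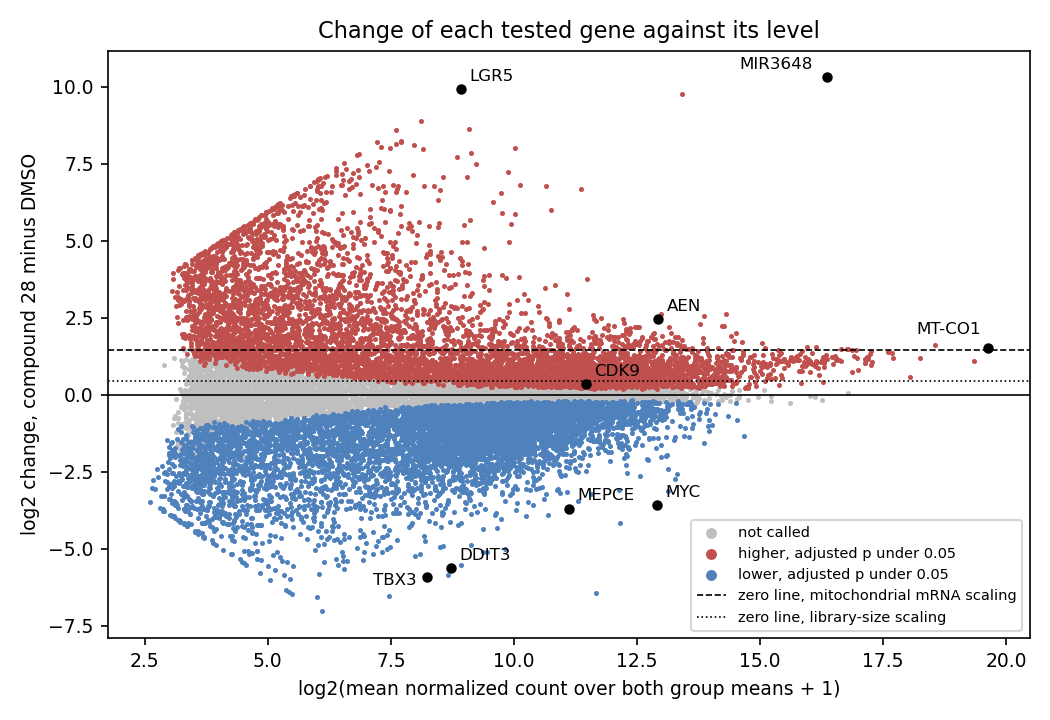
The x axis gives the log2 of the mean normalized count plus 1, the y axis the log2 change (compound 28 minus DMSO), and each point 1 of 18326 genes, coloured by call. The solid line is no change under the authors' normalization, and the dashed and dotted lines show where no change lies when libraries are scaled on mitochondrially encoded mRNAs or on library size: CDK9 lies above the solid line and below the other lines.

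The split into higher and lower genes depended on the scaling. The median log2 change of all genes was -0.03 with the authors' factors, -0.48 with library sizes only, 0.17 with upper-quartile factors, -1.46 with scaling on mitochondrially encoded mRNAs and -1.10 with scaling on ribosomal protein mRNAs. With library sizes only 4257 genes were higher and 9299 lower. Scaling on mitochondrially encoded mRNAs gave 1844 higher and 13867 lower, and scaling on ribosomal protein mRNAs gave 2310 higher and 12280 lower. Directions below are relative to the median gene unless another scaling is named. Mitochondrially encoded genes took 4.17% ± 0.353 of gene reads in DMSO and 8.47% ± 0.522 in compound 28 (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). The 10 most abundant genes took 6.41% ± 0.365 and 11.1% ± 0.346 (SD, n = 3; exact permutation p = 0.1). Of 46 named genes besides CDK9, mitochondrial mRNA scaling turned 13 calls the other way and ended 4, and ribosomal protein scaling turned 5 and ended 11. Library sizes only ended the calls of FEN1, STIP1, ATP5B and DDB1.

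CDK9 mRNA was 2494 ± 241 normalized counts in DMSO and 3156 ± 189 in compound 28 (SD, n = 3), a log2 change of 0.34 ± 0.10 (SE; adjusted p = 0.0085, limma). It passed as higher in the authors' normalization, was not called with library sizes only (log2 change -0.11, adjusted p = 0.34; 2.3e-06 to 1 over all alternatives), and was lower with scaling on mitochondrially encoded mRNAs (-1.11) and on ribosomal protein mRNAs (-0.74). A degrader acts on the protein, so the transcript does not check the labels.

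Genes of P-TEFb and transcription elongation went both ways, with 13 higher, 15 lower and 5 not called among 33 tested, and the same 13 and 15 adjusted over the list alone. MEPCE, which caps and holds the 7SK small nuclear RNA that restrains P-TEFb, fell from 4143 ± 98.9 to 319 ± 36.4 normalized counts (SD, n = 3; log2 change -3.70, adjusted p = 7.6e-09, limma). LARP7, another protein of the 7SK particle, fell with a log2 change of -1.95, and HEXIM1, the P-TEFb inhibitor of that particle, fell 2.07-fold (adjusted p = 1.3e-05). ELL, an elongation factor, rose 2.71-fold, and CCNK, the cyclin of CDK12 and CDK13, had a log2 change of 1.29 that passed, though it was not called under scaling on mitochondrially encoded mRNAs (-0.16). ELL was not called under scaling on mitochondrially encoded or ribosomal protein mRNAs (log2 changes -0.01 and 0.35). The list median was -0.12, turned to 0.09 with upper-quartile factors, and did not differ from other genes (adjusted p = 0.58, camera; 0.76 with an estimated correlation), but passed as lower under mitochondrial mRNA scaling (adjusted p = 0.0258; up to 0.971 over the alternatives), where its median less that of all genes was -0.10, against -0.09. Over 74 genes of RNA polymerase II, the general factors and Mediator, 18 rose, 38 fell and 18 were not called, and 18 and 39 passed adjusted over the list alone. The list was lower than other genes (median log2 change -0.38; adjusted p = 0.031, camera) but had adjusted p = 0.28 with an estimated correlation. Its call was also lost among genes of at least 5 CPM, among protein-coding genes and with upper-quartile factors (adjusted p = 0.179, 0.0782 and 0.0885; 0.00032 to 0.179 over the alternatives). TAF5, a subunit of TFIID, had a log2 change of -3.85. MED13L, the most abundant member, rose 1.78-fold but was lower under scaling on mitochondrially encoded mRNAs (log2 change -0.62).

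**Figure D2:**
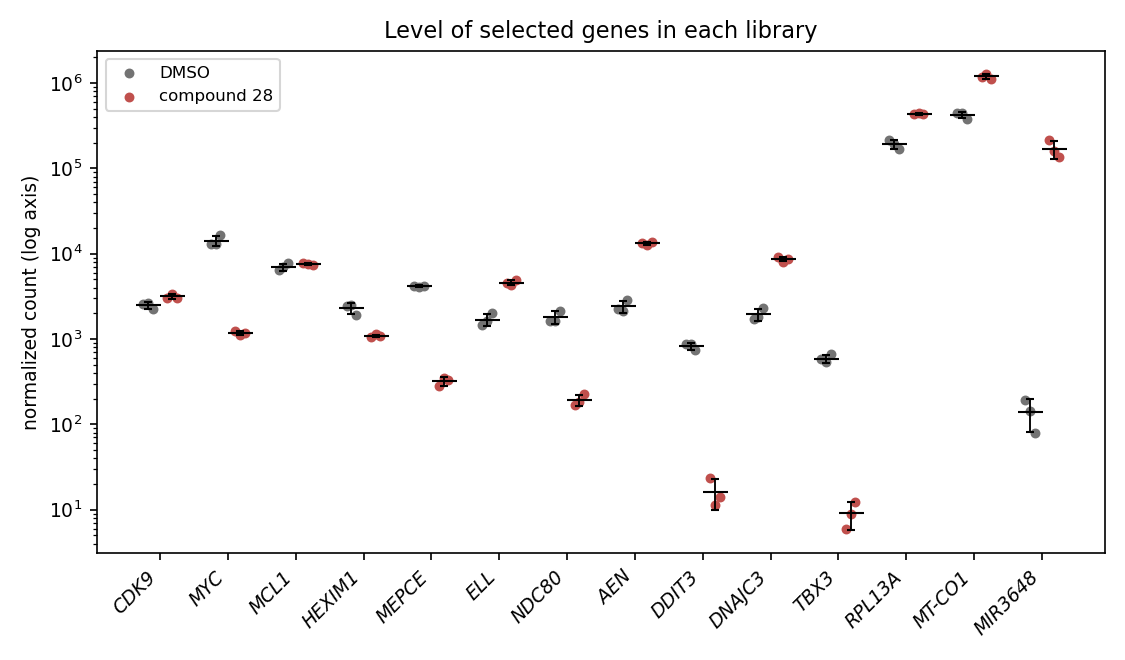
Normalized counts (log axis) of 14 genes, with 1 point per library, grey for DMSO and red for compound 28, a horizontal bar at the mean and error bars of 1 SD (n = 3). MYC, MEPCE, NDC80, DDIT3 and TBX3 lie lower in all 3 compound 28 libraries in the authors' normalization and under every other scaling run, whereas the directions of CDK9 and MCL1 change with the scaling, those of ELL and RPL13A reverse without passing the test under mitochondrial mRNA scaling, and MIR3648 rises from 139 to 169300.

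Immediate early and other short-lived transcripts fell in most cases: of 47 tested, 11 rose, 30 fell and 6 were not called, with 11 and 30 adjusted over the list alone. DUSP1, a MAP kinase phosphatase, had 0 reads in compound 28 and was at least 31.9-fold lower against a floor of 3 reads over the 3 libraries, and FOS had a log2 change of -3.08. ZFP36L1, an RNA-binding protein of AU-rich mRNAs, rose 7.74-fold (adjusted p = 3.3e-07), NR4A3 passed with a log2 change of 5.99, and ARC, with 0 reads in DMSO, was at least 42.5-fold higher. The list was lower than other genes (median -1.27; adjusted p = 0.0038, camera) with adjusted p = 0.24 with an estimated correlation, 0.181 under mitochondrial mRNA scaling and 0.0833 under ribosomal protein scaling (0.00177 to 0.181 over the alternatives), although its median less that of all genes was -1.25 in both scalings and -1.24 in the authors' normalization. Of 26 NF-kB targets 4 rose, 18 fell and 4 were not called, with 4 and 18 adjusted over the list alone. CD83, a surface protein of activated antigen-presenting cells, fell 9.19-fold, and NFKBIA, the feedback inhibitor, had a log2 change of -2.67. The chemokine gene CCL5 rose 2.43-fold, a call lost under scaling on mitochondrially encoded mRNAs (log2 change -0.17) and on ribosomal protein mRNAs (0.19). The NF-kB list was lower (median -1.09; adjusted p = 0.0049, camera), with adjusted p = 0.24 with an estimated correlation and 0.0665 among genes of at least 5 CPM (0.00317 to 0.0665 over the alternatives).

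Among 40 G2/M genes 0 rose, 38 fell and 2 were not called, the same counts as adjusted over the list alone. NDC80, a kinetochore protein, fell 9.25-fold, from 1798 ± 303 to 193 ± 29.1 normalized counts (SD, n = 3; adjusted p = 7.4e-08, limma), with log2 changes of -3.06 for AURKA and -2.49 for CCNB1. BIRC5 (log2 change 0.08) and PRC1 (0.14) were not called, but both passed as higher with upper-quartile factors, PRC1 also without DMSO replicate 3 (0.28), and both as lower with library sizes only and under mitochondrial mRNA scaling (-1.37 and -1.30). The list had the lowest median of those tested (-1.42; adjusted p = 2.5e-10, camera), with adjusted p = 0.42 with an estimated correlation. Among 35 G1/S genes 2 rose, 21 fell and 12 were not called, with 2 and 21 adjusted over the list alone. GINS3, a subunit of the replicative helicase complex, fell 14.3-fold and RRM2, a ribonucleotide reductase subunit, had a log2 change of -2.48. FEN1, a flap endonuclease, rose 1.53-fold, but was lower under scaling on mitochondrially encoded mRNAs (log2 change -0.83) and on ribosomal protein mRNAs (-0.47). The G1/S list was lower (median -0.57, -0.31 without DMSO replicate 3; adjusted p = 0.0020, camera), with adjusted p = 0.67 with an estimated correlation. All of these list medians stayed below 0 under each scaling.

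Among 31 DNA repair genes 6 rose, 18 fell and 7 were not called, with 6 and 18 adjusted over the list alone. RAD52, a recombination mediator, fell 4.28-fold, and BRCA1 had a log2 change of -1.48. ATR, a kinase of the replication checkpoint, rose 1.75-fold, and had a log2 change of -0.64 under scaling on mitochondrially encoded mRNAs. The list was lower (median -0.52, -0.34 without DMSO replicate 3; adjusted p = 0.036, camera), with adjusted p = 0.67 with an estimated correlation. Its call was also lost without DMSO replicate 3 (adjusted p = 0.0616), without compound 28 replicate 3 (0.0634), and among genes of at least 5 CPM (0.142), protein-coding genes (0.0964) and with upper-quartile factors (0.0623). Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail and whose copies are alike, gave 7 higher, 5 lower and 18 not called of 30 tested, 2 of them pseudogenes, with 5 and 4 adjusted over the list alone. HIST1H2BK rose 1.93-fold, with a log2 change of -0.50 under scaling on mitochondrially encoded mRNAs. HIST1H2AC fell by 0.59 on the log2 scale, a call lost without DMSO replicate 1 or replicate 2 (adjusted p = 0.0509 and 0.0518) and with upper-quartile factors (0.078; 1.3e-06 to 0.316 over the alternatives). The histone median was -0.05 (0.23 without compound 28 replicate 3, and 0.01 without the pseudogenes) and its mean 0.01, and camera found no difference from other genes (direction up; adjusted p = 0.87, and 0.89 with an estimated correlation).

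Ribosome biogenesis factors were mostly lower, with 6 higher, 26 lower and 8 not called of 40, the same as adjusted over the list alone. DDX10, a nucleolar helicase, fell 4.94-fold, and POLR1B, the second largest subunit of RNA polymerase I, had a log2 change of -1.80. PPAN, a pre-ribosome factor, rose 3.63-fold (adjusted p = 2.2e-07). The list was lower than other genes (median -0.53; adjusted p = 0.0022, camera), with adjusted p = 0.28 with an estimated correlation. The mRNAs of cytosolic ribosomal proteins moved the other way in the authors' normalization: of 83, 74 rose, 5 fell and 4 were not called, with 74 and 5 adjusted over the list alone. RPL13A, the most abundant, rose 2.26-fold, and its log2 change of 1.18 turned to -0.27 under scaling on mitochondrially encoded mRNAs, where it was not called. The ribosomal protein list was higher (median 1.06; adjusted p = 3.7e-13, camera), with adjusted p = 0.54 with an estimated correlation, and its median was -0.39 under scaling on mitochondrially encoded mRNAs, where camera did not call the list (adjusted p = 0.497; 1.7e-15 to 0.497 over the alternatives), although its median less that of all genes was 1.08 there and 1.09 in the authors' normalization. All 13 mitochondrially encoded mRNAs were higher, also adjusted over the list alone, though by construction not under scaling on themselves, with log2 changes from 1.31 (MT-ND3) to 1.61 (MT-ATP8). MT-CO1 rose 2.85-fold, from 421400 ± 37160 to 1198000 ± 85640 normalized counts (SD, n = 3). That list was higher (median 1.45; adjusted p = 3.3e-06, camera), with adjusted p = 0.31 with an estimated correlation, and also higher with library sizes only (median 1.00). Of 85 matches to nuclear genes of oxidative phosphorylation, 7 of them pseudogenes, 53 rose, 9 fell and 23 were not called, the same as adjusted over the list alone. Without the pseudogenes 49 rose and 8 fell of 78 (median 0.46), and ATP5B rose 1.55-fold. The list was higher (median 0.47; adjusted p = 6.9e-05, camera), with adjusted p = 0.42 with an estimated correlation, but its median was 0.01 with library sizes only and -0.98 under scaling on mitochondrially encoded mRNAs, where ATP5B was lower (log2 change -0.81) and the list lost its call (adjusted p = 0.0851; 4.1e-06 to 0.453 over the alternatives). Its median less that of all genes was 0.50, and 0.48 under both mitochondrial and ribosomal protein scaling.

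**Figure D3:**
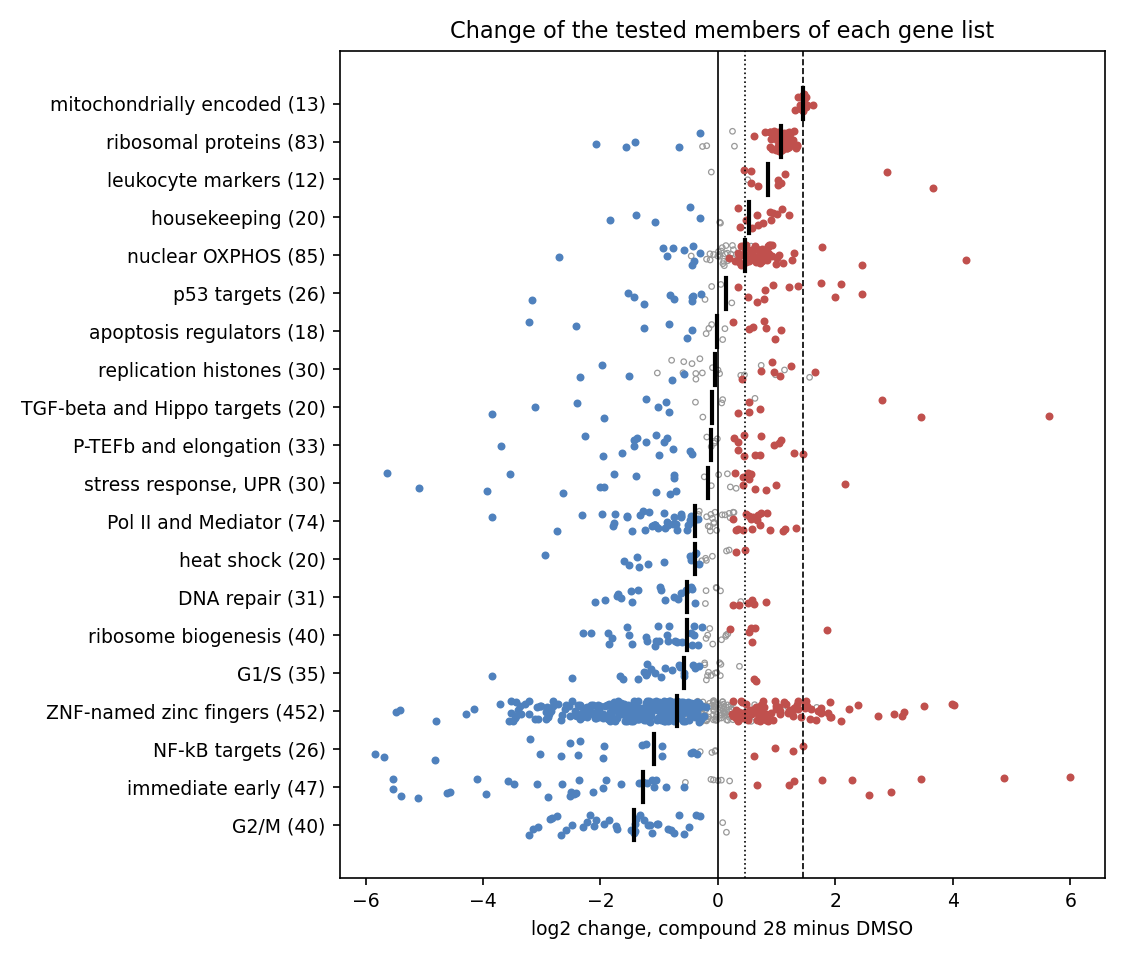
Each point is the log2 change (x axis, compound 28 minus DMSO) of 1 tested member of a gene list (y axis, number tested in brackets), red or blue where called higher or lower and open grey where not called, and black bars are list medians. The solid, dotted and dashed lines mark no change under the authors' normalization, library-size scaling and mitochondrial mRNA scaling: the G2/M median of -1.42 lies left of all 3 lines, and the ribosomal protein median of 1.06 lies between the dotted and dashed lines, so its direction flips under mitochondrial mRNA scaling.

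Known p53 targets went both ways, with 12 higher, 10 lower and 4 not called of 26, the same as adjusted over the list alone. AEN, a nuclease induced by p53, rose 5.49-fold, from 2427 ± 392 to 13220 ± 622 normalized counts (SD, n = 3; adjusted p = 5.8e-08, limma). The log2 changes of CDKN1A (1.99), which inhibits cyclin-dependent kinases, and TP53INP1 (2.10) passed as higher in the authors' normalization and in each other scaling. PLK2, a polo-like kinase, fell 9.02-fold. The list median was 0.14, -0.31 with library sizes only, -1.30 under scaling on mitochondrially encoded mRNAs and -0.94 on ribosomal protein mRNAs, and the list did not differ from other genes (adjusted p = 0.53, camera; 0.67 with an estimated correlation). Of 18 apoptosis regulators 7 rose, 6 fell and 5 were not called, as adjusted over the list alone. MCL1, a short-lived survival protein of the BCL2 family, had 6989 ± 652 normalized counts in DMSO and 7568 ± 211 in compound 28 (SD, n = 3; log2 change 0.12, adjusted p = 0.25, limma). It was called lower with library sizes only (log2 change -0.33), with mitochondrial scaling (-1.33) and with ribosomal protein scaling (-0.97), and higher with upper-quartile factors (0.32) and without DMSO replicate 3 (0.19). BIK, a pro-apoptotic gene, fell 9.24-fold. XIAP, a caspase inhibitor, rose 2.11-fold, and was lower under scaling on mitochondrially encoded mRNAs (log2 change -0.38). The apoptosis list had a median of -0.01 and a mean of -0.22, while camera gave the direction up (adjusted p = 0.91, and 0.91 with an estimated correlation).

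Stress-response transcripts were mixed. Of 30 genes of the integrated stress response and unfolded protein response 10 rose, 14 fell and 6 were not called, with 11 and 14 adjusted over the list alone. DDIT3 fell from 823 ± 71.4 to 16.3 ± 6.4 normalized counts (SD, n = 3), and CHAC1 (-5.10) and TRIB3 (-3.94), other targets of the stress-response factor ATF4, had negative log2 changes that passed. DNAJC3, a co-chaperone of the endoplasmic reticulum, rose 4.47-fold and HSPA5, the main chaperone there, had a log2 change of 0.82. HSPA5 was lower under mitochondrial mRNA scaling (log2 change -0.63), whereas DNAJC3 was called higher in every scaling. The list median was -0.17, 0.03 with upper-quartile factors (adjusted p = 0.22, camera; 0.54 with an estimated correlation), and the list passed as lower under mitochondrial and ribosomal protein scaling (adjusted p = 0.0116 and 0.0123; up to 0.517 over the alternatives), where its median less that of all genes was -0.16, against -0.14. Of 20 heat shock genes 2 rose, 12 fell and 6 were not called, with 1 and 12 adjusted over the list alone. DNAJA1, a co-chaperone, fell 3.04-fold. STIP1, which links HSP70 and HSP90, rose 1.38-fold but was lower under scaling on mitochondrially encoded mRNAs (log2 change -0.99) and ribosomal protein mRNAs (-0.63). The heat shock list was lower (median -0.38; adjusted p = 0.024, camera), with adjusted p = 0.59 with an estimated correlation. That call was also lost among genes of at least 5 CPM (0.132), protein-coding genes (0.0625) and with upper-quartile factors (0.0623; 0.00486 to 0.132 over the alternatives). Of 20 TGF-beta and Hippo targets 7 rose, 8 fell and 5 were not called, as adjusted over the list alone. SMAD7, an inhibitor of TGF-beta signalling, fell 5.30-fold, and TGFBI rose 1.65-fold, with log2 changes of -0.73 and -0.36 under mitochondrial and ribosomal protein scaling. That list did not differ from other genes (median -0.10, 0.11 with upper-quartile factors; adjusted p = 0.88, camera; 0.89 with an estimated correlation).

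Genes with ZNF symbols, most of which encode zinc-finger transcription factors, were lower in most cases, with 90 higher, 272 lower and 90 not called of 452, 13 of them pseudogenes, and 93 and 275 adjusted over the list alone. ZNF572 had a log2 change of -4.80, whereas ZNF516, the most abundant, rose 4.67-fold in the authors' normalization and was called higher in each other scaling. The list was lower (median -0.70, below 0 in each scaling; adjusted p = 4.1e-05, camera), with adjusted p = 0.29 with an estimated correlation. Of 20 housekeeping genes 13 rose, 5 fell and 2 were not called, as adjusted over the list alone. EEF1A1 rose 2.12-fold and GAPDH had a log2 change of 0.93, but both were lower under scaling on mitochondrially encoded mRNAs (-0.37 and -0.52), and 0 of the 20 were called higher in that scaling, where 19 were called lower by limma-trend and the median was -0.92. ACTB was not called (log2 change 0.04), and was lower with library sizes only (-0.41). The housekeeping list missed the threshold (adjusted p = 0.079, camera; 0.67 with an estimated correlation), which it passed without DMSO replicate 3 (0.0381) and among genes of at least 5 CPM (0.0316; up to 0.694 over the alternatives). Of 12 genes of ubiquitin ligases used by degraders 4 rose, 3 fell and 5 were not called, as adjusted over the list alone. CUL2 had a log2 change of -1.79 and CRBN of -0.27, a call CRBN lost with upper-quartile factors (-0.07) and without DMSO replicate 2 or compound 28 replicate 1 or 2 (adjusted p = 0.0954, 0.0561 and 0.0723). DDB1 rose 1.43-fold, a call lost without compound 28 replicate 3 (adjusted p = 0.0501; 0.000266 to 0.679 over the alternatives). DDB1 was lower under scaling on mitochondrially encoded mRNAs (log2 change -0.93) and ribosomal protein mRNAs (-0.57). The ligase list had a median of 0.14 and a mean of -0.02, with the direction up in camera (adjusted p = 0.74, and 0.76 with an estimated correlation).

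Marker genes of cell types were measured in the libraries titled MDA-MB-231. Of 15 leukocyte markers in the table, 7 exceeded 10 CPM in all 6 libraries. LYZ, the lysozyme of myeloid cells, had 500 ± 229 CPM in DMSO and 487 ± 24.7 CPM in compound 28, TYROBP, a signalling adaptor of myeloid and NK cells, 272 ± 62.0 and 396 ± 16.2, and PTPRC, the pan-leukocyte antigen CD45, 108 ± 26.6 and 71.5 ± 5.77 (SD, n = 3 each). Of 26 listed basal and mesenchymal markers, 19 had a row in the table. Of these, 13 exceeded 10 CPM in all 6 libraries, among them MSN, a linker of membrane and actin, with 1045 ± 200 CPM in DMSO. CAV1, caveolin, had 0.0069 ± 0.012 CPM in DMSO and 0.039 ± 0.068 in compound 28. The other members not above 10 CPM were ZEB1 (0.78 CPM in DMSO), SPARC (0.26), FN1 (3.18), AXL (4.44) and FOXC1 (0.020). Whether the 13 abundant members set these cells apart from leukocytes was not tested, so their number does not speak for the line in the titles. Among markers with a row, only 1 of 17 luminal (XBP1), 1 of 13 fibroblast (TAGLN) and 1 of 8 endothelial markers (EGFL7) exceeded 10 CPM in all 6 libraries.

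**Figure D4:**
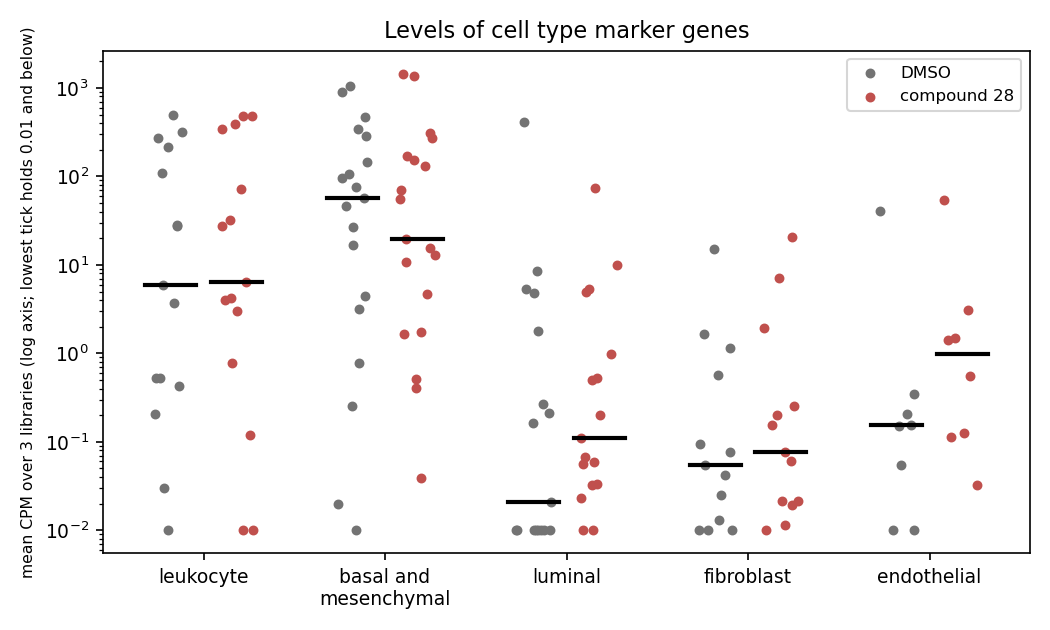
Mean CPM over 3 libraries (log axis; values of 0.01 or less are drawn at 0.01) of each marker gene in 5 cell type lists, grey for DMSO and red for compound 28, with bars at the list medians. In both groups several leukocyte markers lie above 100 CPM, among them LYZ at 500 and 487, while most luminal and fibroblast markers lie below 1 CPM.

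Of 12 leukocyte markers tested, 10 rose, 0 fell and 2 were not called (limma-trend), as adjusted over the list alone. CD4 had a log2 change of 1.07 and CD74 of 1.14, and both were lower under scaling on mitochondrially encoded mRNAs (-0.38 and -0.31). LYZ was not called (log2 change 0.51, adjusted p = 0.079; 3.6e-06 to 0.845 over the alternatives). It passed without DMSO replicate 3 (0.87) and with upper-quartile factors (0.71), and was called lower under scaling on mitochondrially encoded mRNAs (-0.94). The list was higher (median 0.85, -0.60 under scaling on mitochondrially encoded mRNAs and -0.23 on ribosomal protein mRNAs; adjusted p = 0.0040, camera), with adjusted p = 0.24 with an estimated correlation. Under both of those scalings camera did not call the list (adjusted p = 0.181 and 0.0648; 0.00234 to 0.181 over the alternatives), although its median less that of all genes was 0.86 and 0.87 there and 0.88 in the authors' normalization. Of 18 basal and mesenchymal markers 9 rose, 4 fell and 5 were not called, as adjusted over the list alone. PLAU, the urokinase gene, had a log2 change of -2.35, and MSN rose 1.81-fold but was lower under scaling on mitochondrially encoded mRNAs (log2 change -0.59). The list did not differ from other genes (median 0.32, -0.13 with library sizes only, -1.12 and -0.76 under mitochondrial and ribosomal protein scaling; adjusted p = 0.53, camera; 0.67 with an estimated correlation). Of 6 luminal markers tested 2 rose, 3 fell and 1 was not called, as adjusted over the list alone, and XBP1, a transcription factor of the unfolded protein response, fell 4.04-fold. The luminal list had a median of -0.50 and a mean of 0.11 and did not differ from other genes (adjusted p = 0.88, camera; 0.89 with an estimated correlation). All 3 fibroblast and all 4 endothelial markers tested, of 13 and 8 in the table, were called higher, also adjusted over the list alone, too few for a list test. CLDN5, TIE1 and ESAM had 0.055, 0.15 and 0.34 CPM in DMSO and 1.51, 3.13 and 1.43 in compound 28. The filter kept these through compound 28, which favoured rises among tested members. Untested members went both ways, with PDGFRB and ERG lower and VWF and COL1A1 higher on average in compound 28. TAGLN rose 1.86-fold and EGFL7 1.82-fold, with log2 changes of -0.55 and -0.59 under scaling on mitochondrially encoded mRNAs.

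Gene length was compared with the change because CDK9 acts on elongation. Across 17774 genes with an annotated length, which are not independent replicates, Spearman's rho between exonic length and log2 change was -0.06, and it was -0.06, -0.08 and -0.05 in compound 28 replicates 1, 2 and 3 against the DMSO mean. The median log2 change was 0.50 in the shortest of 5 equal bins, -0.15, -0.24 and -0.17 in the middle bins, and 0.08 in the longest. The sign turned among genes with a mean of at least 5 CPM (rho = 0.06) and among protein-coding genes (0.06). With genomic span in place of exonic length rho was -0.04.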

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

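The 2 results of this part were found after the table was opened. Reads counted as aligning to more than 1 place, in a summary row that no comparison in the results uses, made up 20.9% ± 3.96 of all reads in the compound 28 libraries and 11.2% ± 0.278 in the DMSO libraries (SD, n = 3 each). The shares were 25.4%, 18.4% and 18.8% in compound 28 replicates 1 to 3, each above all 3 DMSO libraries (exact permutation p = 0.1, the smallest this design allows). Reads that did not align made up 1.72% ± 0.324 and 1.10% ± 0.0386 (SD, n = 3 each), again with every compound 28 library above every DMSO library (exact permutation p = 0.1).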

How the results depend on the processing

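The edgeR tests on recovered reads and camera on other scalings were chosen after seeing the data. Counts moved with the filter, with a minimum fold and with some scalings, and little with TMM factors (13358 genes called). By scaling, genes raised came to 4257 with library sizes only, 1844 with mitochondrially encoded mRNAs and 2310 with ribosomal protein mRNAs, and genes lowered to 13867 and 12280 with the last pair. At 2-fold or more, mitochondrial mRNA scaling gave 13155 genes (1572 higher, 11583 lower) and ribosomal protein scaling 1880 higher and 9595 lower. Fewer genes tested gave fewer calls: with at least 5 CPM in 3 libraries 8720 (3784 higher), and 3957 at 2-fold (1428 higher, 2529 lower); with protein-coding genes only 5158 at 2-fold (2184 higher). The minimum fold of glmTreat left 8889 genes, 4195 of them higher, by its construction. EdgeR's quasi-likelihood test called 13311 genes with TMM and 13293 with the authors' factors, DESeq2 14574 and limma-voom 13366. Leaving out each library gave 12270 to 13194 calls. Same-numbered libraries had correlations of their deviations from the group means of -0.028, 0.072 and 0.087, and other-numbered ones of -0.131 to 0.105. Pairing by replicate number was thus not seen, but 3 libraries per group are too few to exclude it. With the replicate block 13314 genes were called, 13108 of them also called without it in the same direction. Of the named genes only LYZ gained a call (adjusted p = 0.031, limma-trend).

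CDK9 had a log2 change of -0.11 with library sizes only, 0.32 under glmTreat (not called), -1.11 with mitochondrial mRNA scaling and -0.74 with ribosomal protein scaling, and kept its call in every other setting (adjusted p = 0.000829 to 0.0443). Mitochondrial mRNA scaling reversed 13 named genes: XIAP (-0.38), HIST1H2BK (-0.50), FEN1 (-0.83), STIP1 (-0.99), ATR (-0.64), TGFBI (-0.73), ATP5B (-0.81), MED13L (-0.62), EEF1A1 (-0.37), DDB1 (-0.93), MSN (-0.59), TAGLN (-0.55) and EGFL7 (-0.59). Ribosomal protein scaling reversed FEN1 (-0.47), STIP1 (-0.63), TGFBI (-0.36), ATP5B (-0.45) and DDB1 (-0.57). These reversals follow from the shift of all genes by -1.45 and -1.09 on the log2 scale; of 46 named genes besides CDK9, 27 and 29 kept the same result of the test, called or not. Camera called 13 of 23 lists and 0 with an estimated correlation, where the smallest adjusted p was 0.24. Those losses do not rest on correlation alone. The immediate early list had an estimate of 0.0093, below the preset of 0.01, yet its unadjusted p from camera went from 0.0013 to 0.031. The NF-kB, leukocyte and RNA polymerase II lists also had estimates below the preset, and the other called lists above it. Fry, which asks whether members move on balance 1 way and compares them with no other genes, called 19. The relation to gene length was -0.038 with genomic span, 0.063 with at least 5 CPM and 0.060 with protein-coding genes only, and -0.081 to -0.034 when each library was left out; the cause was not tested. Depth limits low genes: 3 reads were worth 0.055 to 0.11 CPM in single libraries. The 48% of simulated 2-fold changes recovered does not bear on low genes, because changes were planted only in genes above a minimum level.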

Other observations

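The gene lists of the next paragraph and the tests on read-through, on RNAs without a poly(A) tail and on other splits of the libraries were chosen after their results, or the pattern they bear on, had been seen; the marker lists weighed for cell identity and the downstream comparison were written before their levels were looked at.

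Regulators and receptors of blood cells were measured in the libraries. Of 14 transcription factors of the myeloid lineage, 12 exceeded 10 CPM in all 6 libraries, among them MYB with 533 ± 22.7 CPM in DMSO, IRF8 with 583 ± 69.6 and SPI1 with 286 ± 25.8 (SD, n = 3 each). Of the 14, 10 fell and 3 rose, with a list median of -0.67. MEIS1 had a log2 change of -2.39, RUNX3 of -1.96 and GFI1 of -1.64. RUNX1 was higher at 1.32, and was not called under scaling on mitochondrially encoded mRNAs (-0.13), where 13 of the 14 were lower and 0 higher by limma-trend. Of 11 surface receptors 6 exceeded 10 CPM in all 6 libraries, 6 fell and 3 rose. CX3CR1 (8.68 CPM in DMSO) had a log2 change of -5.19, CXCR4 (55.1 CPM) of -5.01 and TLR4 (21.9 CPM) of -4.29, each lower under mitochondrial mRNA scaling too, as were 10 of the 11. Of 6 granule proteins 5 rose and 0 fell in the authors' normalization, but 0 rose and 5 fell under scaling on mitochondrially encoded mRNAs. AZU1 had 1330 ± 259 CPM in DMSO and 2002 ± 49.0 in compound 28, and CTSG 161 ± 18.8 and 255 ± 23.3.

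Leukocyte transcripts were abundant in all 6 libraries, which are titled MDA-MB-231 but carry cell line labels from MDA-MB-231 to MDA-MB-236. A list of 18 genes used throughout blood cells, of which 0 are on another list used here, had a median of 147 CPM in the lowest library and 188 CPM in the highest. Of 16 listed genes of adherent carcinoma cells, the 14 with a row had medians of 1.54 to 2.53 CPM. The most abundant of the blood list were ITGAL with 1617 ± 122 CPM and CYBA with 869 ± 145 CPM in DMSO (SD, n = 3 each), and how many of its genes the labelled line also expresses was not tested, since no library of that line from another source was used. Leukocytes as a minor part of an MDA-MB-231 culture would need the carcinoma list to be the higher, and the blood list was at least 59.5 times the carcinoma list in every library. Cells of a myeloid line in place of the labelled line may account for the blood list at 147 CPM or more. The outcome written down for that case was not fully met, because the carcinoma median lay above 1 CPM. The outcome written down against it was a carcinoma median above 10 CPM, or a blood median under 1 CPM, in each library. Neither was seen in any library. Without a library of the labelled line from another source, this explanation stays open. Of the 14 carcinoma genes 5, YAP1 and CAVIN1 among them, were under 1 CPM in all 6 libraries. Only 1, AKR1B1, was over 10 CPM in all 6. Both groups show the pattern, and no biological explanation of it was tested.

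Many protein-coding genes near 0 in DMSO rose at least 16-fold: 315 with fewer than 20 normalized counts in DMSO could be placed by symbol. Of these, 24.8% (95% Wilson interval 20.3% to 29.8%) had a gene of at least 100 normalized counts ending within 10 kb upstream on the same strand, against 6.59% (5.56% to 7.80%) of 1897 genes of like DMSO level (median 1.18 against 0.863 normalized counts), untested ones included, that changed less than 2-fold. Among tested genes that changed less than 2-fold, whose DMSO level was higher (median 13.7), the share was 11.2% (7.94% to 15.7%), and within 2 kb the share of raised genes, 4.44% (2.67% to 7.32%), lay above that of genes of like level, 1.85% (1.33% to 2.56%), but its interval overlapped that of these tested genes, 3.10% (1.58% to 6.00%). Dense neighbourhoods in general would raise the downstream share alike, but 11.1% (8.10% to 15.1%) of the raised genes had such a gene within 10 kb downstream. That share was 7.33% (6.24% to 8.59%) among the 1897 genes of like level and 9.69% (6.65% to 13.9%) among the tested genes that changed less than 2-fold. Both intervals overlap that of the raised genes, and a smaller part for dense neighbourhoods is not excluded. Read-through from the upstream gene is thus a candidate explanation for part of the rises, as for AOC3 (7.43 kb beyond PSME3), but not for LGR5, whose nearest such gene lay 897 kb away, and raised transcription from the genes' own promoters was not tested and stays open.

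MIR3648 and MIR3687 rose 1265-fold and 879-fold. By RefSeq, a MIR3648 copy lies within the ribosomal RNA precursor gene RNA45SN2, and which copy the table's row counts is not stated. Carry-over of RNA without a poly(A) tail would raise such RNAs alike, but the median log2 change of 8 of them was at most 2.24 in any compound 28 library, with RN7SK at 2.38 and SNORD3A at 2.89 on average. Each of the 8 was higher on average, and of 5 tested 4 were called higher and 0 lower (2 and 0 under mitochondrial mRNA scaling). These values thus speak only against carry-over as the whole of the rise. More of the precursor's spacer RNA and other placement of reads from its copies were not tested and stay open.

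The 6 libraries can be split into 3 and 3 in 10 ways, so a share under 0.05 cannot be reached. The real split gave 13333 called genes and was the only 1 of the 10 to give as many. The highest of the other splits gave 0 calls by limma-trend, with 6 to 70 genes at an unadjusted p under 0.05. Each other split mixes both treatments in both groups, so the treatment difference widens the spread within them. Few calls there follow by construction, and no conclusion is drawn from the contrast.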
